A study of Mus musculus with 6 samples.

How the data were processed

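Gene expression in single cells was measured in 6 mouse stomach tumour samples with the 10x Genomics 3′ kit, version 3, 1 library per sample. The extraction notes in the labels say that tissue was washed in PBS, freed of blood residue and non-tumour tissue, minced and dissociated; no sorting is mentioned. The deposited tables hold raw UMI counts per gene and cell barcode, with no normalization, made by the authors with Cell Ranger 7.0 and the mm10 genome. That unit was checked on the values: all were whole numbers from 0, and totals differed between cells and between libraries. All tables list the same 24579 genes, and every barcode had 400 to 7499 detected genes and under 20% mitochondrial UMIs. The thresholds that gave this are not given in the sources used here.

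Groups were the labels' 3 inflamed tumours (Tff1-CreERT2;Apcfl/fl;Trp53fl/fl mice) and 3 desert tumours (orthotopic allografts in wild-type hosts). Tests, gene lists, cell type markers, the rule for named genes and most alternatives were fixed before the data were examined. A filter of at least 200 genes and at most 20% mitochondrial UMIs removed 0 barcodes. Doublets were scored in each library after the method of Scrublet (neighbours among simulated sums of 2 cells), and the expected number, 0.8% per 1000 cells, was left out by score. This left out 225, 327 and 432 barcodes of the inflamed and 783, 845 and 763 of the desert libraries, and kept 5074, 6071 and 6918 inflamed and 9110, 9435 and 9003 desert cells. Within each group, no library was a copy of another by a chi-square test of their gene totals. Pairs across the groups were not tested.

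Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes gave 30 principal components, a graph of 20 shared neighbours and Leiden clusters at resolution 1. Clusters that were provisionally not epithelial, or held at least 0.3 Ptprc UMIs per 10000, were clustered again with their own variable genes, giving 44 clusters in all. Each cluster with at least 20 cells took the class with the most markers among its top 50 genes by fold change against cells of other provisional classes. This used genes seen in at least 20% of its cells and needed at least 3 detected markers, from 598 of 616 listed markers of 18 classes that were in the tables. This way of naming, and the doublet score, replaced earlier ones after the data were seen. Clusters with at least 2 UMIs per 10000 of both Epcam and Ptprc were left unnamed, a rule also set after the data were seen. It kept out 6 clusters with 3393 cells: 1.77%, 51.1% and 2.17% of the inflamed and 0.132%, 0.212% and 0.178% of the desert libraries. The mixed cells of inflamed library 2 had a median of 974 UMIs. A cluster of 1257 inflamed cells led by neck and chief cell genes (the unnamed neck and chief cluster) was left unnamed by the marker rule, 1.66%, 0.165% and 16.8% of the inflamed libraries. Unnamed cells stayed in the denominator of all shares. The rules named 11 classes.

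Class shares were compared with an exact two-sided permutation test over the 20 assignments of 3 against 3 libraries, whose smallest p is 0.1, and the number of cells per class with edgeR. A share of 1 library has its Clopper-Pearson 95% interval. For gene tests, counts were summed per class and library with at least 10 cells, in the 6 classes with at least 2 such libraries per group and over all kept cells. They were tested with edgeR's quasi-likelihood test (robust, TMM, filterByExpr) and Benjamini-Hochberg adjustment at 0.05. Log2 changes are inflamed minus desert, and their standard error is the size of the change over the root of the F statistic. CPM use TMM-scaled library sizes. Of 35 fixed lists, 32 were tested as results with camera (preset correlation 0.01, Benjamini-Hochberg over the lists with at least 5 tested genes of a class) and again with an estimated correlation. The other lists were checks. A fold against a group with 0 counts is a lower bound, with 3 counts over the group as its floor, and with 1 to 3 counts the ratio is given with its counting interval.

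Genes were named by the rule: adjusted p under 0.05, a log2 change of at least 1 in size, all libraries of one group above the other and at least 20 CPM in the higher group. Their class also had to stand at or above the sum of the other kept cells of that group, so that free RNA is not read as expression. The smallest p gave 10 genes per direction in epithelium and 6 in every other class. Predicted, ribosomal, mitochondrial, haemoglobin, antigen receptor and sex chromosome check genes were left out, and members of the fixed lists could be named in addition. Some genes that met this rule or belong to a list are not reported here. For shares of cells with a UMI, T and NK cells and epithelial cells were thinned to 1000 UMIs, leaving 6760 inflamed and 208 desert T and NK cells, with 223 and 63 shallower ones left out. Positions are from GENCODE vM21, which has the same build, for 24010 of the genes.

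On simulated data with known changes in 200 genes, edgeR recovered 17% of 2-fold and 85% of 4-fold changes in epithelium, 36% and 98% in T and NK cells, 11% and 70% in macrophages and 17% and 84% in endothelial cells. It recovered 7% and 61% in dendritic and 4% and 54% in mast cells. Unchanged genes made up 12.1% of its calls in epithelium, 9.46% in T and NK cells and 5.61% in endothelial cells, above the 5% aimed at, and 1.22%, 4.23% and 0% in macrophages, dendritic and mast cells. The changed genes were drawn only from those with at least 5 expected counts in the smallest library of the class. Recovery of genes with fewer counts was not measured and these rates do not describe it.

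Alternatives were RLE scaling, TMM scaling of cell counts, no low-count filter, DESeq2, a block on the replicate number, a stricter cell filter (500 genes, 10% mitochondrial), doublets kept, Leiden resolutions 0.5 and 2, unnamed cells left out of the denominator, other thinning depths, and leaving out each library in turn. Alternatives chosen after seeing the data were mixed clusters named by their leading genes, cells with at least 1500 UMIs, the neck and chief cluster counted as epithelial, 1 cluster held by both groups for T and NK cells and for macrophages, and epithelium without its neck-led cluster, which is a named epithelial cluster of 1060 cells led by Gkn3, Agr2, Tff2 and Pgc. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.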

Results

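Single-cell RNA sequencing was carried out on mouse stomach tumours of 2 immune types, and the labels call them inflamed and desert. The 3 inflamed tumours arose in the stomach of mice in which Cre under the Tff1 promoter removed floxed Apc and Trp53. The 3 desert tumours were allografts placed in the stomach of wild-type hosts. Immune type and tumour model were therefore the same split of the 6 libraries. Sex-linked genes made that split too: in T and NK cells Ddx3y, on the Y chromosome, stood at 243.6, 179.8 and 203.9 CPM (counts of unique molecular identifiers, or UMIs, scaled to the library total) in inflamed and 0, 0 and 2.79 CPM in desert libraries, and Xist at 0, 0.218 and 0 against 1006, 1232 and 1521 CPM. Every comparison below is between all 3 at once, and none can part them. The inflamed libraries held 5299, 6398 and 7350 cell barcodes with 30801487, 18936643 and 68577447 UMIs (each 1 captured transcript). The desert libraries held 9893, 10280 and 9766 barcodes with 84629138, 77069677 and 102412968 UMIs. Median depth per barcode was 4033, 1466 and 5204 UMIs in the inflamed libraries and 8005, 6699 and 10074 in the desert libraries. The labels do not say whether the 3 replicates of a group are separate animals, so the p-values below measure the spread between these samples.

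The first question was whether the targeted genes differed in the epithelial cells. Apc transcripts stood at 75.8 ± 29.8 CPM (mean ± SD, n = 3) in inflamed and 115 ± 6.08 CPM in desert epithelium, a log2 change of -0.53 ± 0.30 (SE). This difference was not past the threshold (edgeR adjusted p = 0.206), although Apc was lower in each of the 3 inflamed libraries. Trp53 stood at 35.8 ± 1.37 CPM in inflamed and 35.3 ± 7.16 CPM in desert epithelium (log2 change 0.01 ± 0.23, adjusted p = 0.979). A 3′ library may read outside the deleted exons, so these levels check neither deletion.

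The second question was which cells each tumour type held. Immune cells made up 61.9% ± 20.6 (SD, n = 3) of the kept cells of the inflamed tumours and 2.30% ± 1.41 of those of the desert tumours. The shares were 85.2%, 46.0% and 54.4% in the inflamed libraries and 1.09%, 1.97% and 3.84% in the desert libraries. Their difference of 59.6 points gave an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. T and NK cells were the largest named class in the inflamed libraries on average, at 41.1% ± 24.3 of cells, against 0.989% ± 0.668 in the desert libraries (exact permutation p = 0.1). Their share was 68.1% (95% Clopper-Pearson interval 66.8 to 69.4) in inflamed library 1, 34.1% (32.9 to 35.3) in library 2 and 21.1% (20.11 to 22.04) in library 3. In the desert libraries it was 0.439% (0.314 to 0.597), 0.795% (0.626 to 0.995) and 1.73% (1.47 to 2.02). These intervals, and all counting intervals and limits below, cover counting error only. Epithelial cells showed the opposite order, at 11.1% ± 9.58 of inflamed and 96.5% ± 1.93 of desert cells (exact permutation p = 0.1). Of the cells of inflamed library 2, 51.1% lay in mixed clusters that were left unnamed, and its shares depended on them. With those clusters named by their leading genes its share was 55.9% for T and NK cells, 69.4% for immune cells and 28.5% instead of 1.88% for epithelial cells. Among cells with at least 1500 UMIs its T and NK share was 58.7% and its immune share 75.8%. The inflamed epithelial mean was 21.1% with mixed clusters named by their leading genes, 17.35% with the unnamed neck and chief cluster counted as epithelial and 17.9% with doublets kept. Among cells with at least 1500 UMIs the desert mean was 1.475% for immune cells and 0.539% for T and NK cells.

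Several other immune classes were also larger in the inflamed tumours. Neutrophils made up 6.59% ± 4.21 of inflamed and 0.0546% ± 0.0335 of desert cells, B cells 2.56% ± 1.18 and 0.0330% ± 0.0402, and dendritic cells 1.14% ± 0.751 and 0.149% ± 0.112. Each of these differences had an exact permutation p of 0.1. The inflamed shares by library were 5.99%, 2.72% and 11.1% for neutrophils, 3.88%, 2.19% and 1.61% for B cells, and 2.01%, 0.725% and 0.694% for dendritic cells. Among cells with at least 1500 UMIs no desert neutrophil or B cell was left. Plasma cells, which secrete antibody, numbered 534 of 18063 inflamed cells and 0 of 27548 desert cells. A count of 0 allows a share of up to 0.0109%, so the plasma cell share was at least 272-fold higher (3 counts over the desert group), or at least 142-fold without inflamed library 3 and 178.5-fold without desert library 2. Endocrine and tuft cells numbered 68 in the inflamed and 0 in the desert libraries, a share at least 34.6-fold higher, but inflamed library 2 also held 0. That bound was 52.1 without inflamed library 2, 9.89 without inflamed library 3 and 22.7 without desert library 2. Mast cells and basophils made up 2.23% ± 2.80 of inflamed and 0.139% ± 0.158 of desert cells (exact permutation p = 0.3). Inflamed library 3 carried that mean, with shares of 1.24%, 0.0659% and 5.39% in the inflamed and 0%, 0.106% and 0.311% in the desert libraries, and without it the difference of 2.09 points was 0.515. Macrophages and monocytes made up 5.50% ± 3.40 and 0.936% ± 0.414 (exact permutation p = 0.1), with 2.86%, 4.32% and 9.34% in the inflamed libraries.

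Among immune cells alone, T and NK cells made up 64.3% ± 22.3 in the inflamed and 41.9% ± 2.73 in the desert libraries. That difference was within the spread of the inflamed libraries, which stood at 79.9%, 74.1% and 38.7% (exact permutation p = 0.4). Endothelial cells made up 1.39% ± 1.26 of inflamed and 0.416% ± 0.167 of desert cells (exact permutation p = 0.2), with 0.552%, 0.774% and 2.83% in the inflamed libraries. Fibroblasts made up 0.686% ± 1.12 and 0.568% ± 0.402 (exact permutation p = 1). Inflamed library 3 carried that mean too, at 1.98% against 0.0788% and 0% in libraries 1 and 2. The difference of 0.118 points turned direction without it (-0.529) and without desert library 1.

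**Figure D1:**
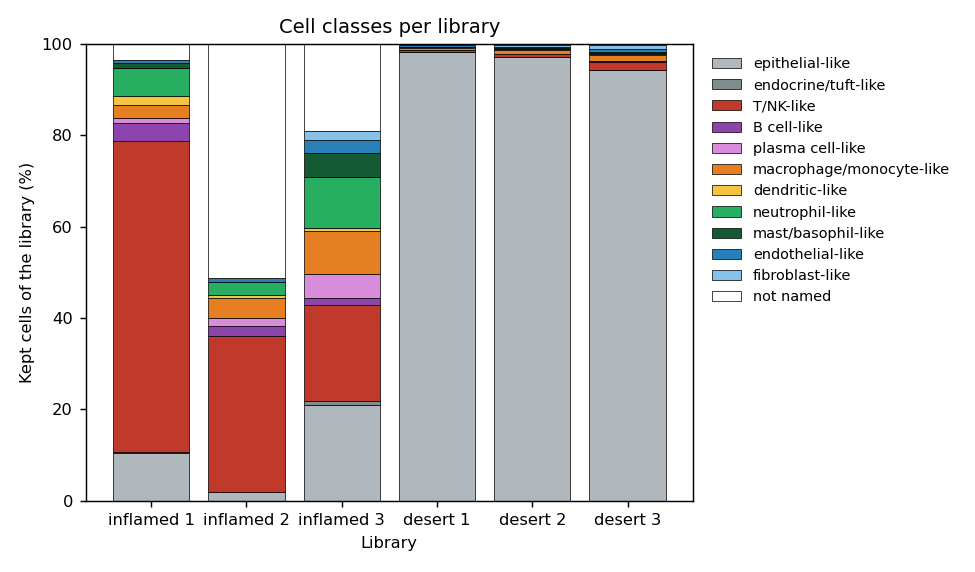
Percent of kept cells (vertical axis, 0 to 100) in each named cell class, 1 stacked bar per library, for the 3 inflamed and 3 desert tumours, with cells left unnamed as a class of their own. Epithelial cells averaged 96.5% of the desert bars and 11.1% of the inflamed bars, and T and NK cells 0.989% and 41.1%.

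A count model over the 11 classes (edgeR, Benjamini-Hochberg) called 8 of them. Higher in the inflamed libraries were plasma cells (adjusted p = 0.000180) and the endocrine-led endocrine and tuft class (adjusted p = 0.00588), both without a desert cell. Neutrophils were higher by a log2 change of 6.87 ± 1.54 (SE; adjusted p = 0.000755), B cells by 6.21 ± 1.58 (adjusted p = 0.00194) and T and NK cells by 5.37 ± 1.43 (adjusted p = 0.00229). Mast cells were higher by 3.99 ± 1.68 (adjusted p = 0.0459) and dendritic cells by 2.93 ± 1.31 (adjusted p = 0.0476), while epithelial cells were lower (log2 change -3.12 ± 1.30, adjusted p = 0.0438). In these 8 classes the 3 inflamed libraries did not all lie apart from the 3 desert libraries for mast cells and for endocrine and tuft cells; in the other 6 they did. Macrophages (2.55 ± 1.24, adjusted p = 0.0608), endothelial cells (1.73, adjusted p = 0.187) and fibroblasts (0.28, adjusted p = 0.856) were not past the threshold.

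With TMM scaling of the cell counts the calls of B cells (2.32), T and NK cells (1.36) and endocrine and tuft cells (6.19) were lost, and dendritic (-1.21) and mast cells (-0.53) turned direction. The calls of dendritic, epithelial and mast cells were also lost at Leiden resolution 2 (2.94, -3.14 and 3.99) and with the replicate number as a block (2.96, -3.63 and 3.78). The block also ended the endocrine and tuft call (7.42), doublets kept ended the dendritic (2.95) and epithelial (-2.43) calls, and naming the mixed clusters ended the mast cell call (3.99). The dendritic call ended without inflamed library 1 or any 1 desert library (2.24 to 3.40 over the leave-one-out fits). The epithelial call ended without inflamed library 1 or 2 or any 1 desert library (-3.96 to -2.61), and the mast cell call without inflamed library 3 or desert library 1 or 2 (2.22 to 5.35).

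The third question was how the epithelial cells of the tumour types differed. Genes of MHC class II, which presents antigen to helper T cells, were tested first. Cd74, its invariant chain, reached 1528 ± 898 CPM (mean ± SD, n = 3) in inflamed and 6.91 ± 3.17 CPM in desert epithelium (log2 change 7.78 ± 0.65, adjusted p = 2.68e-05). H2-Eb1 reached 533 ± 338 against 1.35 CPM (8.60 ± 0.79, adjusted p = 5.24e-05), and H2-Ab1 521 ± 441 against 0.931 CPM (9.09 ± 1.17, adjusted p = 0.000937). Ciita, the transcriptional activator of these genes, was at 16.0 ± 10.1 against 0.799 ± 0.126 CPM (4.11 ± 0.53, adjusted p = 0.000407). Of 10 MHC class II genes tested, 9 were higher and 1, the costimulator Cd80, lower, both adjusted over the list alone and over all genes. The median log2 change was 5.40 (camera adjusted p = 1.81e-07; 0.201 with an estimated correlation). Among MHC class I genes, H2-K1 rose to 1952 ± 638 from 765 ± 275 CPM (1.35 ± 0.40, adjusted p = 0.0280) and H2-D1 to 1151 ± 445 from 338 ± 130 CPM (1.76 ± 0.42, adjusted p = 0.0107). B2m was higher on average but its libraries overlapped, at 1778, 3543 and 523 CPM in inflamed and 199, 424 and 759 CPM in desert epithelium (adjusted p = 0.0442). Of the 19 genes of the class I list, 16 were higher over all genes and 19 adjusted over the list alone (median 1.74, camera adjusted p = 1.13e-08; 0.288 with an estimated correlation).

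Genes of the interferon response and chemokines were tested next. The GTPases Gbp2 (91.3 ± 52.9 against 0.111 CPM, log2 change 9.50 ± 0.62, adjusted p = 8.82e-06) and Iigp1 (273 ± 199 against 1.78 CPM, 7.21 ± 0.71, adjusted p = 8.11e-05) were higher in all 3 inflamed libraries. So was Cxcl9, a ligand that draws T cells, at 81.8 ± 75.6 against 0.160 CPM (8.71 ± 0.81, adjusted p = 0.000116). Of 26 interferon gamma response genes, 22 were higher and 0 lower by either adjustment. Their median log2 change was 2.65 (camera adjusted p = 7.54e-12; 0.201 with an estimated correlation). Of the interferon alpha response genes, 6 of 27 were higher and 1, Stat2, lower over all genes, with 4 higher and 1 lower adjusted over the list alone (median 0.59). Their camera adjusted p was 0.00647, or 0.618 with an estimated correlation. Among T cell recruiting chemokines 6 of 9 genes were higher over all genes and 7 adjusted over the list alone (median 3.71, camera adjusted p = 8.79e-05; 0.288 with an estimated correlation). Among myeloid recruiting chemokines and cytokines 12 of 15 were higher over all genes and 13 adjusted over the list alone (median 5.001, camera adjusted p = 5.54e-06; 0.201 with an estimated correlation). Cx3cl1 (18.96 ± 2.65 against 3.91 ± 1.60 CPM) and Cxcl1 (66.5 ± 65.3 against 6.12 CPM) were among them, and Cxcl5 had 0 desert counts and was at least 601-fold higher (1092 without inflamed library 3 and 368.5 without desert library 3). The inflamed epithelial class also carried transcripts of immune cells, with Gzma at 28.7 ± 27.8 CPM against 0.404 and the antibody gene Igkc at 676 ± 582 CPM against 7.54. Each list member was held against the other kept cells of the group where it was higher. In epithelium 7 of 19 class I, 6 of 10 class II, 12 of 26 interferon gamma response and 12 of 27 interferon alpha response genes stood at or above that level. Of the chemokine lists, 2 of 9 T cell recruiting and 4 of 15 myeloid recruiting genes did. For the other members of these lists, B2m among them, RNA of other cells cannot be told apart from expression in the epithelium.

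Gastric lineage genes marked the inflamed epithelium. Tff2, a secreted peptide of neck cells, reached 5942 ± 4320 CPM in inflamed and 0.0872 ± 0.0375 CPM in desert epithelium (log2 change 15.99 ± 0.97, adjusted p = 5.85e-06). The pit cell genes Tff1 (506 ± 252 against 0.0227 CPM, 14.18 ± 0.88, adjusted p = 6.51e-06), Gkn1 (390 ± 256 against 0.0963 CPM, 11.83 ± 1.09, adjusted p = 0.000102) and Cldn18 (253 ± 68.9 against 4.45 ± 1.12 CPM, 5.81 ± 0.37, adjusted p = 6.85e-06) were higher. Cblif (113 ± 70.0 against 0.0788 CPM) and Muc6 (429 ± 260 against 57.7 ± 46.4 CPM) were too. Of 12 pit cell genes, 11 were higher by either adjustment (median 8.61, camera adjusted p = 2.39e-13; 0.147 with an estimated correlation). Only 1 of these 12 stood at or above its level in the other cells of the group where it was higher. The other inflamed cells include the unnamed neck and chief cluster. Of 9 neck, chief and parietal cell genes, 6 were higher over all genes and 7 adjusted over the list alone (median 2.90, camera adjusted p = 6.50e-05; 0.221 with an estimated correlation). Intestinal metaplasia genes were higher in 8 of 12 cases and lower in 1 by either adjustment (median 4.94, camera adjusted p = 1.55e-05; 0.201 with an estimated correlation). Vil1 (80.9 ± 17.9 against 3.04 ± 0.78 CPM, 4.72 ± 0.32, adjusted p = 9.28e-06) was higher and Reg4 (1.132 ± 1.502 against 52.4 ± 20.9 CPM, -7.20 ± 0.59, adjusted p = 2.41e-05) lower. Squamous and basal keratin genes were higher in 7 of 8 cases and lower in 1, Krt17, by either adjustment (median 4.74, camera adjusted p = 8.79e-05; 0.201 with an estimated correlation). Krt14 (19.8 ± 10.9 against 0.0780 CPM) and Sfn (147 ± 47.7 against 16.6 ± 4.19 CPM) were higher.

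Wnt target genes split in direction. Desert epithelium held more of the stem cell receptor Lgr5 (932 ± 73.9 against 127 ± 81.0 CPM in inflamed; log2 change -2.83 ± 0.47, adjusted p = 0.00168). The Wnt inhibitors Notum (950 ± 547 against 207 ± 99.1 CPM, -2.19 ± 0.54, adjusted p = 0.0127), Apcdd1 (192 ± 54.8 against 39.8 ± 12.3 CPM, -2.19 ± 0.34, adjusted p = 0.00104) and Wif1 (395 ± 68.8 against 138 ± 30.2 CPM, -1.496 ± 0.301, adjusted p = 0.00480) were also lower in inflamed epithelium. Cd44 was higher (386 ± 123 against 87.6 ± 18.9 CPM, 2.14 ± 0.33, adjusted p = 0.00119), as was Myc (40.1 ± 14.1 against 12.9 ± 4.02 CPM, 1.63 ± 0.35, adjusted p = 0.00640). Of 26 Wnt target genes, 6 were higher and 9 lower over all genes, and 7 higher and 11 lower adjusted over the list alone. As a list they were not past the threshold (median -0.51, camera adjusted p = 0.367). The p53 target list also split, with 10 of 28 genes higher and 6 lower over all genes and 11 and 8 adjusted over the list alone (camera adjusted p = 0.174). Pmaip1 (57.1 ± 27.4 against 0.338 CPM) and Fas (39.1 ± 1.59 against 2.03 CPM) were higher, and Bax was lower (128 ± 11.6 against 214 ± 11.4 CPM, -0.75 ± 0.25, adjusted p = 0.0469).

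**Figure D2:**
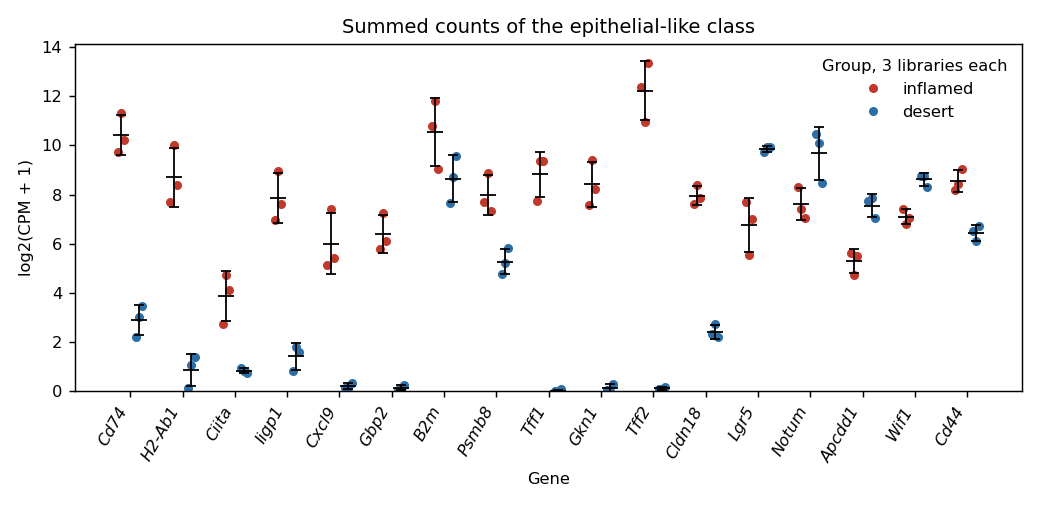
Level of 17 genes in the epithelial class as log2 of CPM plus 1 (vertical axis), 1 point per library, with the mean and SD of the 3 inflamed and of the 3 desert libraries. Cd74 averaged 1528 CPM in inflamed and 6.91 CPM in desert epithelium, and Lgr5 127 and 932 CPM.

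By the rule for named genes, which takes the smallest p, the 10 genes higher in inflamed epithelium included the hydrogen peroxide producing pair Duoxa2 and Duox2. Duoxa2 (mm10, chromosome 2, 122298900 to 122302885) was at 40.4 ± 7.13 against 0.0413 CPM (log2 change 9.82 ± 0.38, adjusted p = 2.40e-06), and Duox2 (chromosome 2, 122279247 to 122298449) at 48.2 ± 12.5 against 0.0553 CPM (9.72 ± 0.42, adjusted p = 2.41e-06). Anxa3 (114 ± 16.5 against 0.308 CPM), Serpinb5 (60.7 ± 21.8 against 0.0555 CPM), Muc4 (77.5 ± 14.5 against 0.190 CPM) and the potassium channel subunit Kcne3 (350 ± 217 against 0.0238 CPM) came with them. The complement genes C4b (114 ± 19.8 against 0.297 CPM) and Cfb (27.6 ± 7.40 against 0.174 CPM), Wdr72 (37.2 against 0.182 CPM) and St8sia6 (127 ± 53.5 against 0.0256 CPM) completed the 10. Desert epithelium expressed Hmcn1, a basement membrane protein (chromosome 1, 150562524 to 150993435), at 472 ± 87.6 CPM against 3.65 ± 1.12 (log2 change -6.93 ± 0.41, adjusted p = 5.30e-06). It also expressed Comp (170 ± 45.3 against 2.26 CPM), Shisa9 (85.8 ± 16.1 against 0.454 CPM), the cannabinoid receptor Cnr1 (73.8 against 0.117 CPM) and the Wnt inhibitor Sfrp5 (34.3 ± 3.45 against 0.468 CPM). Cpne7 (58.8 against 1.94 CPM), Tspan32 (53.2 against 0.276 CPM) and Cldn10 (51.7 against 0.674 CPM) were among them too. Mrap had 0 inflamed counts and was at least 384-fold lower (118.2 without inflamed library 3), and Arsi had 3 inflamed counts, with a desert to inflamed ratio of 330 (counting interval 113 to 1601). For each of these 20 genes, as for every gene the rule names in other classes, all libraries of one group lay above all of the other. The matricellular gene Sparc was lower in inflamed epithelium (4.88 against 302 ± 114 CPM), and Id1 (903 ± 127 against 24.3 ± 16.4 CPM) and Id3 (722 ± 154 against 28.7 CPM) were higher.

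Of the 32 lists, 21 were called in epithelium, each with most of its called members higher in inflamed tumours. Complement (8 of 12 genes higher over all genes; 8 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.41e-07, 0.147 with an estimated correlation) was one. NF-kB and TNF response (14 of 20 higher over all genes, 15 adjusted over the list alone) had a camera adjusted p of 2.57e-06, or 0.296 with an estimated correlation. Macrophage proinflammatory genes (11 of 18 higher and 1 lower; 13 and 1 adjusted over the list alone) had 7.95e-06, or 0.221 with an estimated correlation. Junction and keratin genes (7 of 21 higher and 1 lower; 9 and 1 adjusted over the list alone) had 0.000356, or 0.288 with an estimated correlation. Cldn4 (283 ± 220 against 24.2 ± 3.36 CPM) and Cldn7 (510 ± 152 against 81.7 ± 22.9 CPM) led that list. TGF beta signalling (8 of 19 higher and 1 lower by either adjustment) had 0.0149, or 0.355 with an estimated correlation. Cytotoxic genes (5 of 8 higher, 6 adjusted over the list alone) had 0.00114, or 0.323 with an estimated correlation. Of these 8 genes, 0 stood at or above the level of the other cells of the group where they were higher. Inhibitory receptors (5 of 10 higher, 5 higher and 1 lower adjusted over the list alone) had 0.0216, or 0.254 with an estimated correlation, and 2 of 10 at that level.

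Weaker epithelial calls went to inhibitory ligands (5 of 15 genes higher and 1 lower by either adjustment; camera adjusted p = 0.0131, 0.206 with an estimated correlation). Myc targets (2 of 30 higher; 0 adjusted over the list alone) had 0.0179, or 0.502 with an estimated correlation. Oxidative phosphorylation (1 of 25 higher, Uqcrh; 0 adjusted over the list alone) had 0.0225, or 0.697 with an estimated correlation. Dissociation stress genes (5 of 20 higher; 4 adjusted over the list alone) had 0.0387, or 0.697 with an estimated correlation. Some epithelial list calls ended without 1 library: oxidative phosphorylation without inflamed library 2 (0.570) or any 1 desert library (0.0544, 0.0866 and 0.0829), and Myc targets without inflamed library 2 (0.284) or desert library 1 or 2 (0.150 and 0.0558). Dissociation stress ended without inflamed library 1 or 3 (0.152 and 0.0640) or desert library 1 or 2 (0.0709 and 0.201), and interferon alpha response (0.0861) and inhibitory receptors (0.0530) without desert library 2. Lists not past the threshold were cell cycle (0 of 34 higher and 3 lower over all genes, 0 adjusted over the list alone; camera adjusted p = 0.887), hypoxia and glycolysis (0.981), EMT (0.485), extracellular matrix (0.963), myofibroblast (0.0681) and inflammatory fibroblast genes (0.0784). Macrophage alternative genes (0.0578), naive and memory T cell genes (0.960) and endothelial activation genes (0.789) were not past it either.

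In epithelium 5016 of 16909 genes tested changed, 2579 higher and 2437 lower in the inflamed tumours, over 2101 inflamed and 26599 desert cells. Of these, 3618 stood in the higher group at or above the level of the other kept cells of that group, 1568 higher and 2050 lower. The median log2 change over all genes tested was -0.08. The groups shared almost no epithelial cluster. Of 534, 114 and 1453 inflamed cells, 271, 95 and 691 lay in a cluster led by Gkn3, Agr2, Tff2 and Pgc. It held 0, 3 and 0 desert cells. Another, led by Ntng1 and Cldn4, held 259, 18 and 757 inflamed and 0 desert cells. Without the first of these, which is not the unnamed neck and chief cluster, the Myc target and oxidative phosphorylation lists were no longer called and turned direction.

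The fourth question was how T and NK cells differed between the tumour types, over 6983 inflamed and 271 desert cells. The groups lay in different clusters of this class: 1 cluster, led by Ikzf2, Tnfrsf9 and Tnfrsf4, held 30 of 40, 65 of 75 and 116 of 156 desert cells, but 53 of 3454, 25 of 2072 and 107 of 1457 inflamed cells. Over the whole class, inflamed cells had higher levels of Gzma, Ifng, Ctla4 and Cd40lg. Gzma, a cytotoxic granule protease, stood at 2350 ± 894 CPM in inflamed and 195 ± 209 CPM in desert cells (mean ± SD, n = 3; log2 change 3.61 ± 0.71, edgeR adjusted p = 0.0344). Ifng stood at 842 ± 363 against 297 ± 88.2 CPM (1.52 ± 0.36, adjusted p = 0.0212), the checkpoint receptor Ctla4 at 699 ± 125 against 234 ± 64.6 CPM (1.52 ± 0.28, adjusted p = 0.00350), and Il7r at 535 ± 61.6 against 253 ± 68.5 CPM (1.14 ± 0.28, adjusted p = 0.0225). The chromatin organiser Satb1 was at 916 ± 427 against 111 ± 34.5 CPM (3.08 ± 0.37, adjusted p = 0.000119). The helper ligand Cd40lg (chromosome X, 57212143 to 57224042) was at 108 ± 9.32 CPM with 0 desert counts, at least 18.3-fold higher (6.38 without desert library 3). The cytokine Il17a had 11372 counts in inflamed and 0 of 547127 UMIs in desert cells, at least 64.7-fold higher (22.6 without desert library 3); it was singled out after its values were seen. Il12rb2 (267 ± 31.8 against 34.8 ± 10.3 CPM, 2.88 ± 0.33, adjusted p = 5.33e-05), Acpp (183 ± 36.8 against 9.98 CPM) and the heat shock gene Hsph1 (chromosome 5, 149614287 to 149636376; 1145 ± 310 against 102 ± 39.2 CPM, 3.41 ± 0.34, adjusted p = 1.52e-05) were higher too. Gcnt2 had 3 desert counts and an inflamed to desert ratio of 21.1 (counting interval 7.22 to 102).

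Desert T and NK cells expressed more of the inhibitory receptor Pdcd1 (chromosome 1, 94038305 to 94052553), at 176 ± 31.1 against 37.3 ± 11.1 CPM (log2 change -2.21 ± 0.29, adjusted p = 0.000229). The pore-forming Prf1 was at 214 ± 136 against 29.5 ± 1.72 CPM (-2.68 ± 0.35, adjusted p = 0.000234), and the exhaustion regulator Tox at 663 ± 176 against 282 ± 134 CPM (-1.25 ± 0.33, adjusted p = 0.0350). Nrp1 (108 against 18.7 CPM), Il10ra (93.3 against 18.7 CPM), Arsb (200 against 53.9 CPM) and Atp2b2 (40.4 ± 21.7 against 0.476 CPM) were higher in desert cells as well. Tumour genes were also higher there, with Sox9 at 67.8 ± 15.1 against 5.29 CPM, Notum at 95.6 against 2.48 CPM and Epcam at 131 ± 7.69 against 23.9 ± 16.7 CPM (-2.46 ± 0.48, adjusted p = 0.0124). The Epcam level of desert T and NK cells was 16.5%, 17.2% and 9.11% of that of the epithelial class of the same library.

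Subset markers were tested one by one, and 8 of 21 were past the threshold. Higher in inflamed cells were Ctla4, Cd40lg, Il2ra (log2 change 1.20, adjusted p = 0.0274) and the gamma delta T cell gene Tcrg-C1, which had 0 desert counts and was at least 7.41-fold higher (2.59 without desert library 3). Lower were the NK receptor genes Klrb1c (-2.44, adjusted p = 0.0238), Klra4 (-2.69, adjusted p = 0.0119), Klra8 (-3.62, adjusted p = 0.00275) and Klra7 (-2.58, adjusted p = 0.0344). Klrb1c was lower in all 3 inflamed libraries, while desert library 1 had 0 counts of each of the other 3. Trdc (3.75, adjusted p = 0.0513), Cd4 (1.15, adjusted p = 0.0682), Eomes (-1.38, adjusted p = 0.0847), Cd8a (0.58, adjusted p = 0.611) and Foxp3 (-1.55, adjusted p = 0.532) were not past it. Il2ra lost its call without inflamed library 1 or 2 or any 1 desert library (1.03 to 1.44), Klrb1c without inflamed library 2 or desert library 1 or 2 (-2.56 to -1.68), and Klra4, Klra7 and Klra8 each without desert library 2 or 3 (-2.20 and -2.66, -2.49 and -1.89, -3.01 and -3.65). The calls of Klra4 (-2.64) and Klra7 (-2.48) also ended without inflamed library 2, and that of Klra7 without desert library 1 (-2.80). The count of 8 became 4 without inflamed library 2 and 15 without inflamed library 3, and 5, 3 and 4 without desert library 1, 2 and 3.

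With every T and NK cell thinned to 1000 UMIs, 37.7% ± 3.78 of inflamed and 19.3% ± 4.08 of desert cells had a Ctla4 UMI. The same shares were 42.5% ± 10.8 and 11.03% ± 7.71 for Satb1, 27.5% ± 8.25 and 5.29% ± 2.75 for Gzma, and 37.2% ± 3.79 and 16.8% ± 2.48 for Il7r. For Pdcd1 they were 3.04% ± 0.976 and 11.6% ± 4.001, for Prf1 2.78% ± 0.220 and 9.03% ± 2.37, and for Klrb1c 0.644% ± 0.0243 and 7.22% ± 4.66. Each of these 7 differences had an exact two-sided permutation p of 0.1. Cd8a shares were 12.9% ± 7.62 and 12.8% ± 7.95 (exact permutation p = 1), and their difference of 0.0613 points turned direction at 2000 UMIs (-1.82), without inflamed library 1 and without desert library 2. Il17a was seen in 4.66%, 10.2% and 16.4% of inflamed cells and in 0 of 26, 51 and 131 desert cells. Epithelial cells, for comparison, had shares of 0.846% and 1.17% for Satb1, 1.06% and 1.08% for Ctla4, 3.66% and 0.0236% for Gzma and 0.533% and 0.0314% for Il7r in inflamed and desert libraries. Their shares were 0% and 0.00747% for Pdcd1, 0.0253% and 0.00403% for Prf1, 0% and 0% for Klrb1c, and 0.0505% and 0% for Il17a. In desert epithelium Satb1 and Ctla4 stood far above Il7r and Pdcd1, which argues against RNA of T and NK cells as their source. Without thinning the T and NK shares were 70.8% and 12.6% for Satb1, 66.7% and 25.0% for Ctla4, 34.0% and 4.53% for Gzma and 70.2% and 26.7% for Il7r. They were 10.4% and 26.1% for Pdcd1, 9.76% and 10.7% for Prf1, 1.73% and 8.91% for Klrb1c, 26.4% and 15.4% for Cd8a, and 14.7% and 0% for Il17a. Median depth was 3938, 4300 and 4121 UMIs in inflamed and 1249, 1305 and 1709 in desert T and NK cells, against 6890, 2709 and 4268 in inflamed and 7862, 6581 and 10088 in desert epithelial cells.

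**Figure D3:**
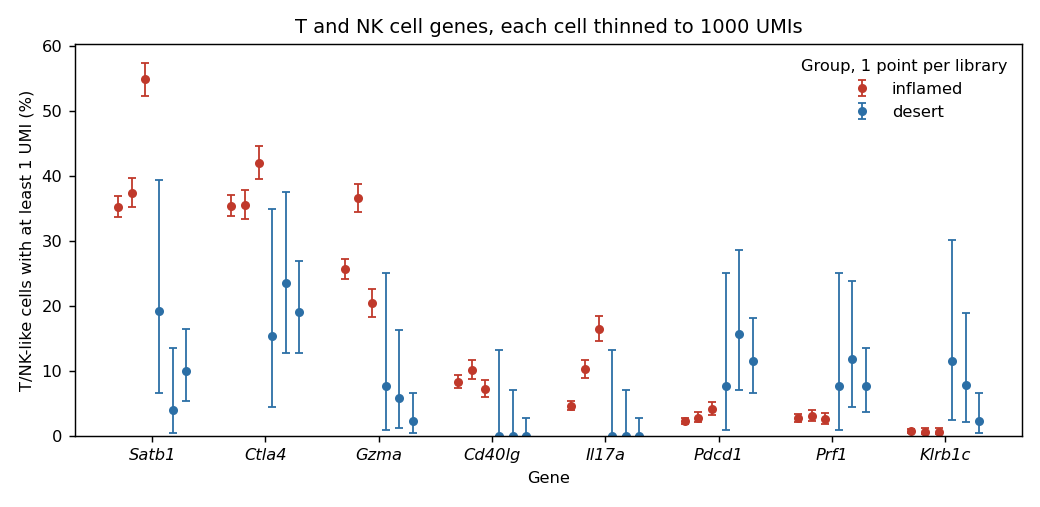
Percent of T and NK cells with at least 1 UMI of each of 8 genes after thinning to 1000 UMIs per cell (vertical axis), 1 point per library with its exact binomial 95% interval, for 3 inflamed and 3 desert libraries. Satb1 averaged 42.5% of inflamed and 11.03% of desert cells, and Pdcd1 3.04% and 11.6%.

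Of the 32 lists, 6 were called in T and NK cells. Lower in inflamed cells were junction and keratin genes (0 of 15 higher and 4 lower; 0 and 7 adjusted over the list alone; camera adjusted p = 1.49e-05, 0.515 with an estimated correlation), with 0 of 15 at or above the level of other desert cells. Wnt targets (1 of 17 higher and 8 lower; 1 and 9 adjusted over the list alone) had 3.80e-05, or 0.515 with an estimated correlation, and 4 of 17 at that level. Oxidative phosphorylation (0 of 25 higher and 1 lower, Ndufa4, by either adjustment) had 1.49e-05. Hypoxia and glycolysis (0 of 24 higher and 4 lower, or 3 and 8 adjusted over the list alone) had 0.000611, and both had 0.641 with an estimated correlation. Macrophage alternative genes (1 of 13 higher and 3 lower, or 1 and 6 adjusted over the list alone) had 0.0103, or 0.515 with an estimated correlation. Of these, 4 of 25, 9 of 24 and 4 of 13 stood at that level. Higher were myeloid recruiting chemokines (2 of 8 higher and 0 lower; 3 and 1 adjusted over the list alone; 0.00154, or 0.522 with an estimated correlation). Their median log2 change was 4.88, or 0.94 with 4 genes at their bound. This call ended without desert library 1 (0.117), that of hypoxia and glycolysis without inflamed library 1 (0.0533) and that of macrophage alternative genes without desert library 2 (0.116). Not past the threshold were cytotoxic genes (3 of 18 higher and 1 lower; 4 and 3 adjusted over the list alone; camera adjusted p = 0.467), inhibitory receptors (1 of 13 higher and 2 lower; 3 and 5 adjusted over the list alone; 0.249) and naive and memory genes (3 of 10 higher by either adjustment; 0.0854). Dissociation stress genes (8 of 20 higher; 9 adjusted over the list alone; 0.0639), among them Hspa1a (1645 ± 924 against 87.0 ± 38.6 CPM, 4.15 ± 0.47, adjusted p = 0.000243), were not past it as a list.

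In T and NK cells 631 of 10979 genes changed, 334 higher and 297 lower in inflamed cells. Of these, 308 of the higher and 74 of the lower genes stood at or above the level of the other kept cells of the same group. The median log2 change was 0.12, and 0.07 with RLE scaling, so directions are relative to that shift. The count was 332 without inflamed library 2, and 328, 220 and 419 without desert library 1, 2 and 3; DESeq2 called 952 genes, of which 42.7% were higher against 52.9% with edgeR. In the 1 cluster that held most desert T and NK cells Pdcd1 (-1.62) and Prf1 (-6.46) stayed lower and Satb1 (3.08) and Ctla4 (2.21) higher in inflamed cells, but Ifng (-2.87) and Tox (1.12) turned direction. Nkg7 (-3.14) and Ccl5 (-3.69) were lower in inflamed cells there, and the subset markers Cd8a, Cd8b1, Foxp3 and Ikzf2 turned direction. That cluster therefore did not hold 1 subset, and these values are not changes within 1 subset.

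The fifth question was how macrophages and monocytes differed, over 1053 inflamed and 257 desert cells. The groups lay partly in different clusters: 1 cluster, led by Apoe, C1qa and Trem2, held 55 of 55, 74 of 76 and 115 of 126 desert cells and 70, 248 and 98 inflamed cells. The other clusters held 38, 3 and 330, and 37, 11 and 218 inflamed cells. Over the whole class, inflamed macrophages had higher levels of Cd74, H2-Ab1 and Il1b, and desert macrophages of Ctsd, Apoe and Trem2. Cd74 was at 7671 ± 1823 CPM in inflamed and 1686 ± 1048 CPM in desert macrophages (mean ± SD, n = 3; log2 change 2.19 ± 0.50, edgeR adjusted p = 0.0281). H2-Ab1 (3048 ± 686 against 587 ± 403 CPM, 2.37 ± 0.57, adjusted p = 0.0411) and H2-Eb1 (4162 ± 872 against 754 ± 539 CPM, 2.46 ± 0.62, adjusted p = 0.0487) were higher, and Ciita had 1 desert count, with a ratio of 66.5 (counting interval 11.9 to 2635). The cytokine Il1b (1933 ± 1354 against 131 ± 39.4 CPM, 3.87 ± 0.65, adjusted p = 0.00954) and the chemokine Ccl3 (1619 ± 1396 against 359 ± 107 CPM, 2.17 ± 0.55, adjusted p = 0.0471) were higher. By the rule, the heat shock genes Hspa1a (1714 ± 628 against 182 ± 8.36 CPM, 3.24 ± 0.37, adjusted p = 0.000448) and Hspa1b (1457 ± 698 against 89.9 ± 60.3 CPM), and Zmynd15 (192 against 27.7 CPM), were also higher. The nuclease Dnase1l3 had 2 desert counts, with a ratio of 41.8 (counting interval 11.5 to 346), and Frmpd4 had 0 and was at least 16.1-fold higher (8.61 without desert library 3).

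Desert macrophages expressed the protease Ctsd (chromosome 7, 142375911 to 142388038) at 7343 ± 2732 CPM against 462 ± 128 in inflamed macrophages (log2 change -3.98 ± 0.39, adjusted p = 0.000336). The lipid carrier Apoe was at 56230 ± 39150 against 9588 ± 4077 CPM (-2.55 ± 0.56, adjusted p = 0.0252), Trem2 at 1007 ± 469 against 132 ± 51.2 CPM (-2.90 ± 0.43, adjusted p = 0.00295) and Gpnmb at 1658 ± 987 against 64.2 CPM (-4.56 ± 0.97, adjusted p = 0.0311). Fabp5 (2772 ± 842 against 267 CPM), Spp1 (1488 ± 530 against 253 ± 206 CPM) and Ctsb (5939 ± 987 against 1251 ± 305 CPM) were higher in desert macrophages too. So were Mfge8 (288 ± 131 against 15.5 CPM), the proton pump subunit Atp6v0d2 (310 ± 63.7 against 20.3 CPM), Serpinb6a (218 against 17.2 CPM), Rhoc (159 against 10.1 CPM) and Gng11 (71.1 against 3.07 CPM). The tumour genes Lgr5 (69.6 against 4.62 CPM) and Notum (104 against 6.87 CPM) were also higher in desert macrophages, and the gastric gene Tff1, with 0 desert counts, was at least 27.7-fold higher in inflamed ones (17.2 without inflamed library 3 and 14.8 without desert library 3).

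**Figure D4:**
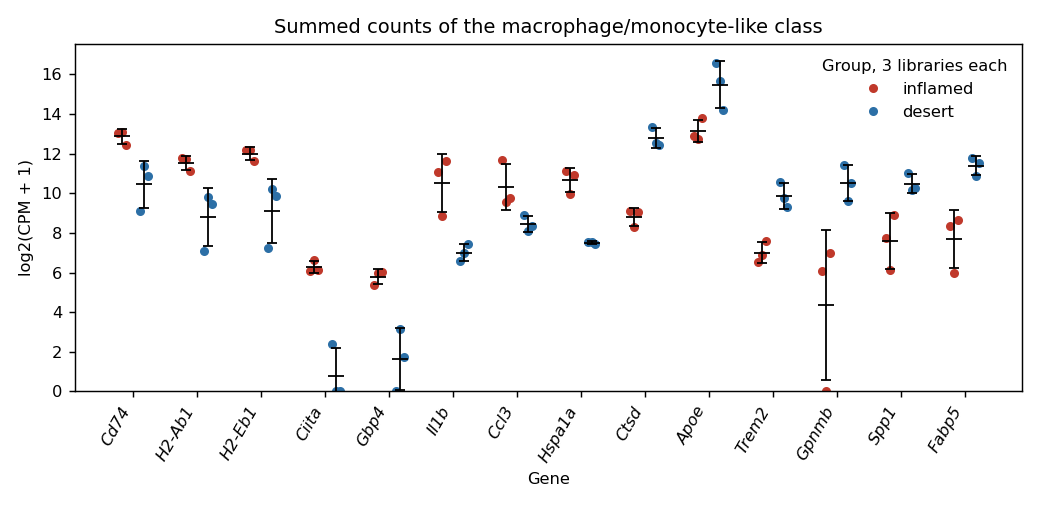
Level of 14 genes in the macrophage and monocyte class as log2 of CPM plus 1 (vertical axis), 1 point per library, with the mean and SD of the 3 inflamed and of the 3 desert libraries. Il1b averaged 1933 CPM in inflamed and 131 CPM in desert macrophages, and Ctsd 462 and 7343 CPM.

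Of the 32 lists, 15 were called in macrophages. Higher in inflamed cells were interferon gamma response genes (7 of 22 over all genes, 18 adjusted over the list alone, 0 lower; camera adjusted p = 6.61e-10, 0.0730 with an estimated correlation). MHC class II genes (6 of 10, 8 adjusted over the list alone) had 5.27e-06, or 0.0730 with an estimated correlation. Proinflammatory genes (5 of 16, 7 adjusted over the list alone) had 2.34e-05, MHC class I genes (1 of 17, 6 adjusted over the list alone) 0.00199, and NF-kB and TNF response genes (3 of 18 higher and 1 lower, 5 and 1 adjusted over the list alone) 0.00225. Each of these 3 had 0.473 with an estimated correlation. T cell recruiting chemokines (1 of 6, 3 adjusted over the list alone) had 0.0105 and TGF beta signalling (3 of 13 higher and 1 lower by either adjustment) 0.00988, again 0.473 with an estimated correlation. Lower in inflamed cells were macrophage alternative and lipid associated genes (0 of 21 higher and 10 lower; 1 and 11 adjusted over the list alone; median -1.95), with a camera adjusted p of 6.94e-08, or 0.473 with an estimated correlation. Of these 21 genes, 20 stood at or above the level of other desert cells. Wnt targets (0 of 9 higher and 4 lower; 1 and 5 adjusted over the list alone; 0.00988, or 0.473 with an estimated correlation) were lower with 1 of 9 at that level. Hypoxia and glycolysis (0 of 20 higher and 2 lower; 0 and 5 adjusted over the list alone; 0.00983, or 0.677 with an estimated correlation) and junction and keratin genes (0 of 7 higher and 1 lower; 0 and 3 adjusted over the list alone; 0.0491, or 0.473 with an estimated correlation) were lower too. Myc targets (0.0228), cell cycle (0.0159), inflammatory fibroblast (0.0398) and dissociation stress genes (0.0377) were called higher, with 0.473, 0.583, 0.480 and 0.677 with an estimated correlation. Dissociation stress lost its call without inflamed library 1 or 3 or desert library 2 or 3 (0.147, 0.173, 0.114 and 0.0729), and cell cycle without inflamed library 1 or 2 (0.0670 and 0.132). Myc targets (0.0538) and inflammatory fibroblast genes (0.226) lost it without inflamed library 1, TGF beta signalling (0.0900) without inflamed library 3, and junction and keratin (0.0777) and hypoxia and glycolysis (0.390) without desert library 3. Complement genes (camera adjusted p = 0.697) and myeloid recruiting chemokines (0.482) were not past the threshold.

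In macrophages 339 of 5510 genes changed, 164 higher and 175 lower in the inflamed tumours, and 119 and 122 of them stood at or above the level of the other kept cells. The count was 208 without inflamed library 1, and 148, 103 and 160 without desert library 1, 2 and 3. In the 1 cluster held by both groups it was 132, where Ctsd (-2.29), Atp6v0d2 (-1.88), Serpinb6a (-2.04) and Rhoc (-1.86) were not past the threshold, nor were Apoe (-1.75), Trem2 (-1.82), Gpnmb (-2.04), Fabp5 (-1.23), Spp1 (-1.07), Ctsb (-1.61) and Ccl3 (0.69). Of the 15 list calls 6 held there, those of MHC class I, MHC class II, interferon gamma response, Myc targets, hypoxia and glycolysis and alternative and lipid associated genes.

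Endothelial cells were compared over 271 inflamed and 114 desert cells. Inflamed endothelium expressed more Selp, Icam1 and Iigp1, and desert endothelium more Cldn5 and Gpihbp1. The leukocyte adhesion genes Selp (1064 ± 355 against 58.6 ± 18.2 CPM, log2 change 4.10 ± 0.46, adjusted p = 1.26e-05) and Icam1 (1081 ± 466 against 96.4 ± 18.4 CPM, 3.46 ± 0.47, adjusted p = 9.61e-05) were higher in inflamed cells. The interferon-induced GTPase Iigp1 (525 ± 76.0 against 50.2 ± 36.2 CPM, 3.25 ± 0.47, adjusted p = 0.000223) was higher as well. Gbp2 had 0 desert counts and was at least 15.9-fold higher (9.60 without desert library 1 and 8.69 without desert library 3), and Ehd3 had 2, with a ratio of 34.3 (counting interval 9.39 to 285). The tight junction gene Cldn5 (693 ± 359 against 37.0 ± 41.7 CPM, -3.62 ± 0.55, adjusted p = 0.000689) and the lipase anchor Gpihbp1 (1820 ± 467 against 131.4 ± 145.1 CPM, -3.44 ± 0.57, adjusted p = 0.00206) were higher in desert cells. Mtss1 (222 against 25.4 CPM), Depp1 (741 against 80.2 CPM), Mest (258 against 24.6 CPM) and Cd109 (144 against 13.8 CPM) were too. The 7 lists called included interferon gamma response (4 of 10 higher, 8 adjusted over the list alone; camera adjusted p = 3.91e-08, 0.228 with an estimated correlation) and NF-kB and TNF response (5 of 13, 9 adjusted over the list alone; 1.84e-08, 0.228 with an estimated correlation). MHC class I genes (2 of 12, 7 adjusted over the list alone; 1.83e-05, 0.401 with an estimated correlation) and macrophage proinflammatory genes (1 of 6, 4 adjusted over the list alone; 3.84e-05, 0.228 with an estimated correlation) were also higher. Dissociation stress (0 of 20 by either adjustment; 0.00478, 0.648 with an estimated correlation) and TGF beta signalling (1 of 12 by either adjustment; 0.0484, 0.401 with an estimated correlation) were higher, and oxidative phosphorylation (0 of 24 by either adjustment; 0.0365, 0.676 with an estimated correlation) was lower. Endothelial activation genes were not past the threshold (2 of 18 higher and 1 lower; 2 and 2 adjusted over the list alone; 0.604). In all 127 of 3643 genes changed, 72 higher and 55 lower, of which 47 and 41 stood at or above the level of the other kept cells. The count was 247 without inflamed library 3, and 57, 58 and 52 without desert library 1, 2 and 3; the list count was 12 without desert library 3. With doublets kept 218 genes changed. Cd109 lost its call without desert library 3 (-2.91), oxidative phosphorylation without inflamed library 3 (0.469) or desert library 1 or 2 (0.0594 and 0.0611), TGF beta signalling without inflamed library 1 (0.224) or desert library 1 (0.0730), and dissociation stress without inflamed library 1 (0.201) or desert library 2 (0.154).

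Dendritic cells were compared over 3 inflamed and 2 desert libraries, and mast cells over 2 and 2. Inflamed dendritic cells expressed more Ifitm1 (1344 ± 256 CPM, SD, n = 3, against 280 ± 29.7, n = 2; log2 change 2.27 ± 0.43, edgeR adjusted p = 0.0155). Plac8 had 1 desert count, with a ratio of 179 (counting interval 32.1 to 7086), and Specc1 had 3, with a ratio of 8.48 (2.87 to 41.3). Desert dendritic cells expressed more of the chemokine Ccl6 (587 ± 533 against 21.6 CPM, -4.67 ± 0.60, adjusted p = 0.00118) and of the retinoic acid enzyme Aldh1a2 (274 ± 47.3 against 11.8 CPM, -4.17 ± 0.61, adjusted p = 0.00162). Ear2 (391.9 against 4.755 CPM), Plpp1 (194 against 20.2 CPM), Hist1h2bc (549 against 86.7 CPM) and Sgms1 (807 against 197 CPM) were also higher in desert cells. Of 4193 genes 28 changed, 6 higher and 22 lower, of which 3 and 13 stood at or above the level of other cells. Called lists were interferon gamma response (0 of 14 by either adjustment; camera adjusted p = 0.00162, 0.7997 with an estimated correlation) and naive and memory genes (0 of 7, 4 adjusted over the list alone; 0.00162, 0.767 with an estimated correlation). TGF beta signalling (0 of 9, 4 adjusted over the list alone; 0.0370, 0.767 with an estimated correlation) and NF-kB and TNF response (0 of 18, 3 adjusted over the list alone; 0.0212, 0.7997 with an estimated correlation) were higher too. Junction and keratin genes (1 of 5 lower, 2 adjusted over the list alone; 0.00601, 0.767 with an estimated correlation) and hypoxia and glycolysis (0 of 16, 3 lower adjusted over the list alone; 0.0284, 0.7997 with an estimated correlation) were lower. The gene count was 17 and 87 without inflamed library 2 and 3, and 4 and 10 without desert library 2 and 3; the list count of 6 was 2 without inflamed library 1, 0 without desert library 2 and 10 without desert library 3. Single calls ended without 1 library for Ccl6 (desert library 2, -3.12), Aldh1a2 (desert libraries 2 and 3, -4.24 and -3.83) and Ifitm1 (desert libraries 2 and 3, 2.48 and 2.34). They also ended for Hist1h2bc (inflamed libraries 1 and 2, -2.48 and -2.60, and desert library 3, -1.70). Plpp1 (-3.63 to -1.64) and Sgms1 (-2.17 to -1.50) lost theirs without inflamed library 1 or 2 or desert library 2 or 3, and Specc1 (2.95 to 3.82) without inflamed library 2 or desert library 2 or 3. With 18 genes under the stricter cell filter, 51 with the replicate block, 45 with DESeq2 and 156 without a low-count filter, this count depended on each of those settings.

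Inflamed mast cells expressed the mucosal proteases Mcpt1 and Mcpt2. Mcpt1 stood at 26350 ± 1133 CPM (SD, n = 2) with 0 desert counts, at least 329-fold higher (96.2 without desert library 3), and Mcpt2 at 27440 ± 6250 against 2716 ± 1505 CPM (log2 change 3.30 ± 0.45, edgeR adjusted p = 0.000242). Hspa1a (3280 ± 562 against 155 ± 118 CPM, 4.20 ± 0.59, adjusted p = 0.000382), Dnajb1 (2762 against 191 CPM) and Thsd4 (2935 against 231 CPM) were higher, and Hsph1 had 2 desert counts, with a ratio of 32.3 (counting interval 8.94 to 267). Lsamp (579 against 5.79 CPM), Grik2 (246 against 2.41 CPM), Lgals1 (630 ± 23.5 against 28.1 CPM), Ctla2a (7006 against 949 CPM), Speer4e (889 against 23.8 CPM) and Pstpip2 (176 against 6.15 CPM) were higher in desert mast cells. Of 2852 genes 154 changed, 77 in each direction, of which 70 higher and 61 lower stood at or above the level of other cells; the median log2 change was 0.33, and 0.22 with RLE scaling. Oxidative phosphorylation (0 of 17 by either adjustment; camera adjusted p = 1.92e-05, 0.457 with an estimated correlation) and hypoxia and glycolysis (1 of 15 higher and 3 lower by either adjustment; 0.0251, 0.577 with an estimated correlation) were lower. Macrophage proinflammatory genes (2 of 7, 5 adjusted over the list alone; 0.0251, 0.577 with an estimated correlation) were higher. The gene count was 46 and 97 without inflamed library 1 and 3, 33 and 18 without desert library 2 and 3, and 99 with DESeq2; the list count of 3 was 1 and 0 without desert library 2 and 3. Without desert library 3 Lsamp (-5.66), Lgals1 (-3.70), Ctla2a (-2.13) and Speer4e (-1.85) lost their calls, Speer4e also without inflamed library 1 (-4.80).

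With all kept cells of a library summed, 8708 of 19522 genes differed, 4707 higher and 4001 lower in the inflamed tumours, and these sums mix the classes in their unequal shares. Cytotoxic genes (17 of 18 higher by either adjustment; camera adjusted p = 2.41e-07, 0.506 with an estimated correlation) and interferon gamma response genes (22 of 27 higher and 1 lower; 23 and 1 adjusted over the list alone; 7.56e-08, 0.506 with an estimated correlation) were higher. MHC class II genes (10 of 10 higher by either adjustment; 3.13e-06, 0.506 with an estimated correlation) were higher as well. Wnt targets were lower (3 of 26 higher and 18 lower; 3 and 19 adjusted over the list alone; 5.72e-05, 0.506 with an estimated correlation). In all, 21 of the 32 lists were called in these sums.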

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

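In this part, all tests on the 3 weighed patterns and all counts over splits were chosen after the results were seen; the tests of the difference between cell classes were not. A pair of gene lists moved in opposite directions in different cell classes. Junction and keratin genes were higher in inflamed epithelium and lower in inflamed T and NK cells, and the test of that difference between classes gave an adjusted p of 5.91e-08. With an estimated correlation the calls behind it were lost (adjusted p = 0.288 and 0.515). Over all genes 7 of 21 members were higher in epithelium and 4 of 15 lower in T and NK cells. Against macrophages, where the list was also lower (0.473 with an estimated correlation), the test gave 0.0187. Oxidative phosphorylation genes were higher in inflamed epithelium and lower in inflamed T and NK cells (adjusted p = 1.48e-07) and endothelial cells (adjusted p = 0.0406). With an estimated correlation these calls were lost too (0.697, 0.641 and 0.676), and over all genes 1 of 25 members passed in epithelium, 1 of 25 in T and NK cells and 0 of 24 in endothelial cells. For list oxidative phosphorylation in epithelial, direction times -log10 adjusted p, the value turned to -0.468 without the epithelial cluster led by Gkn3 and Tff2 and to -0.0730 with mixed clusters named. In T and NK cells 0 of 15 junction and keratin genes stood at or above their level in other desert cells.

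Lgr5, Notum and Apcdd1 were lower in inflamed epithelium. Dilution by the epithelial cluster led by Gkn3, Agr2, Tff2 and Pgc (271, 95 and 691 inflamed cells) was argued against by its small share of UMIs in inflamed libraries 1 and 3. The cluster that remained held 4711635 of 5786942 class UMIs in library 1 and 12150735 of 13903698 in library 3. Leaving out the other could therefore change the levels of these libraries little. In library 2 the remaining cluster had only 18 cells, with 92717 of 411095 UMIs. Without the Gkn3-led cluster the highest of the 3 log2 changes was -2.02, with an upper limit of -1.02. A complete lack of Wnt target expression in the inflamed cells that remained was argued against too. Pooled over libraries, their CPM was 8.39-fold (Lgr5) to 157-fold (Notum) that of the unnamed neck and chief cluster of 1257 cells outside the class. Both clusters were defined on expression in these same cells, so the size of this ratio does not measure Wnt activity. In inflamed libraries 1 and 3, the 2 with enough cells of both, the ratio was 32.1 and 6.73 for Lgr5, 186 and 122 for Notum and 58.6 and 70.5 for Apcdd1, with a lowest counting bound of 6.11. A mix of tumour and other epithelial cells inside that remaining cluster stays open, as do tumour model, immune type and sex-linked gene pattern, which the design does not part and which are untested.

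Hspa1a was higher in inflamed libraries. Stress of the whole suspension during preparation is a candidate explanation, since Hspa1a was higher by over 2 SE in 6 of 6 classes. An immediate-early response to dissociation was argued against: of 42 values for 7 immediate-early genes in 6 classes only 1 was higher and past the threshold, with a median log2 change of -0.15. Shallow droplets were argued against by macrophages with at least 1500 UMIs, where the log2 change of Hspa1a was 3.35 (edgeR adjusted p = 0.000407). Tumour model, immune type, sex-linked gene pattern and any difference in handling stay open, untested.

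Many genes were higher in desert T and NK cells. For the 223 of them below their level in other desert cells, RNA of tumour cells cannot be told apart from expression: for 42.6% (95 genes; interval 36.0 to 49.4) the whole difference lay within the desert epithelial level times the Epcam share that these cells carried, on average 14.3%. The other 74 were left out of this test, whose outcome their selection would fix; among them, Prf1 stood at 168 CPM in desert T and NK cells and 0.0429 CPM in other desert cells, and Pdcd1 at 174 and 0.0343 CPM. Another mix of T and NK subsets cannot be told apart: 5 of the 6 named genes stayed lower in the 1 cluster with most desert cells, but Nkg7 (-3.14) and Ccl5 (-3.69) differed there too, so that cluster did not hold 1 subset. Such a mix stays open for genes higher in inflamed cells too, since Ifng turned to -2.87 there, and tumour model, immune type and sex-linked gene pattern stay open, untested.

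The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. For genes changed, the real value and the highest of the other splits were 5016 and 0 in epithelium, 631 and 4 in T and NK cells, 339 and 0 in macrophages, 127 and 1 in endothelial cells, and 8708 and 0 over all cells; in each, 1 split of the 10, the real one, gave as many. For lists they were 21 and 22 in epithelium (2 splits gave as many, the real one included), 6 and 9 in T and NK cells (4 splits), 15 and 12 in macrophages (1 split), 7 and 9 in endothelial cells (5 splits) and 21 and 25 over all cells (4 splits). For cell classes they were 8 and 0 (1 split).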

How the results depend on the processing

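Alternatives chosen after seeing the data, and so tests that were not planned, were mixed clusters named, the minimum of 1500 UMIs, the neck and chief cluster as epithelial, 1 cluster held by both groups, and epithelium without its neck-led cluster; for every change below without a stated reason the cause was not tested. Immune shares kept direction and side of the threshold in 25 of 25 values, shares per class in 142 with 2 reversed, class abundance in 116 with 25 weaker, 2 stronger and 8 reversed, and named genes in 1167 with 34 weaker. Shares of T and NK cells with a UMI of a subset marker stayed in 163 values and moved in 13, of Cd8a, Cd8b1, Eomes, Gata3 and Ncr1. Counts of genes changed stayed within 1.5 times in 76 values and moved in 33; counts of lists stayed in 92 and moved in 17. Single lists kept their call in 798 values, with 153 weaker and 4 reversed.

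Class abundance (log2 change) with TMM scaling of cell counts was 2.32 for B cells, 1.36 for T and NK, -1.21 for dendritic, 6.19 for endocrine and tuft, -2.67 for endothelial, -4.43 for fibroblasts, -1.68 for macrophages and -0.53 for mast cells. With doublets kept, where a Pgc-led cluster was named epithelial, it was 2.95 for dendritic and -2.43 for epithelial cells, and endothelial genes numbered 218. At Leiden resolution 2 it was 2.94 for dendritic, -3.14 for epithelial and 3.99 for mast cells; at 0.5 it was 2.62 for macrophages, now past the threshold, and Trp53 stood at -0.0086. With the replicate block, abundance was 2.96 for dendritic, 7.42 for endocrine and tuft, -3.63 for epithelial, -1.58 for fibroblasts and 3.78 for mast cells; genes numbered 968 in T and NK and 51 in dendritic cells, and dendritic lists 3. Equal replicate numbers did not pair: same-number correlations in epithelium were 0.00213, -0.0622 and -0.129. With mixed clusters named, abundance was 2.55 for macrophages, now past the threshold, and 3.99 for mast cells, list oxidative phosphorylation in epithelial, direction times -log10 adjusted p, was -0.0730 and Trp53 -0.023.

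Without a low-count filter genes numbered 1423 in T and NK cells, 931 in macrophages, 324 in endothelial and 156 in dendritic cells, lists 11 in T and NK and 14 in endothelial cells, subset markers 13, and Trp53 stood at -0.078; the counts differ because more genes were tested. DESeq2 gave 952 genes in T and NK, 45 in dendritic and 99 in mast cells, and Trp53 at -0.040; RLE scaling gave Trp53 at -0.039. In 1 cluster held by both groups, which has fewer cells, genes numbered 382 in T and NK cells and 132 in macrophages, macrophage lists 6 and macrophage named genes 5; the macrophage NF-kB list (direction times -log10 adjusted p) was -0.0922, and Cd8a (-3.62), Cd8b1 (-3.15), Foxp3 (2.35), Ikzf2 (2.26) and Il1rl1 (2.15) reversed. The stricter filter gave 18 dendritic genes. An estimated correlation left 0 lists in each class and over all cells. Without the neck-led cluster list Myc target in epithelial, direction times -log10 adjusted p, was -0.0219, list oxidative phosphorylation in epithelial, direction times -log10 adjusted p, was -0.468 and Trp53 -0.024.

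Leaving out 1 library in turn, where fewer samples remain, gave -0.529 to 0.461 points for the fibroblast share; abundance of 2.24 to 3.40 for dendritic, -3.96 to -2.61 for epithelial, -3.85 to 0.94 for fibroblasts and 2.22 to 5.35 for mast cells; genes of 220 to 768 in T and NK, 103 to 484 in macrophages, 52 to 247 in endothelial, 4 to 87 in dendritic and 18 to 97 in mast cells; lists of 5 to 12 in endothelial, 0 to 10 in dendritic and 0 to 3 in mast cells; Trp53 of -0.10 to 0.18; subset markers of 3 to 15; and named genes of 2 to 9 in dendritic and 6 to 10 in mast cells. No value could be had for mast cells with the block (no residual degrees of freedom), the stricter filter or at least 1500 UMIs, nor for dendritic cells at Leiden resolution 0.5. Where 1 library of a group was left, it was assumed to vary like the others. Median depth was 1249, 1305 and 1709 UMIs in desert T and NK cells, 1140 and 1098 in desert mast cells of libraries 2 and 3, and 969 in endothelial cells of inflamed library 2.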

Other observations

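In this part the clusters and genes were chosen after their values were seen, and no explanation of them was tested. Inflamed tumours held a cluster of gamma delta like T cells led by Il17a, Trdc, Cd163l1 and Il23r, with 101, 108 and 148 cells in the 3 libraries. They also held a cluster of 1257 cells led by Pgc, Clps, Tff2, Reg1 and Muc6, with 84, 10 and 1163 cells; no desert cell fell in it. Its Tff2 level was 37798 CPM and its Lgr5 level 20.3 CPM, against 4131 and 170 CPM in the inflamed epithelial cluster of 1034 cells that showed more Wnt target expression. The endocrine cells of inflamed libraries 1 and 3 expressed Chga, Chgb and Ghrl.

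Sex-linked and imprinted genes also split with the groups. Scaled to plain class totals, Ddx3y stood at 96.2, 36.5 and 73.5 CPM in inflamed epithelium and 2.11, 2.85 and 2.75 CPM in desert epithelium. Eif2s3y had 0 counts in desert epithelium and was at least 4323-fold higher in inflamed (2652 without desert library 3). Xist stood at 0.682, 0.719 and 1.23 CPM in desert epithelium but at 1138, 1296 and 1533 CPM in desert T and NK cells and 886, 1192 and 1645 CPM in desert endothelial cells, and near 0 in the inflamed libraries. Igf2 stood at 195, 535 and 1231 CPM in desert epithelium against 0.864, 0 and 0.863 CPM in inflamed, and H19 at 115, 468 and 703 CPM against 8.64, 0 and 0.791 CPM.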
